A study of Homo sapiens with 6 samples.

How the data were processed

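Extracellular vesicles (EVs) shed by UM-UC-3, an established human bladder carcinoma cell line, were the source material. Per the labels' protocols, vesicles carrying the integrin subunit ITGA6 were pulled out of the total vesicle pool with magnetic beads coated with an antibody to ITGA6, and RNA was extracted from these vesicles and from vesicles labelled control. How the control vesicles were obtained is not given in the sources used here. Per the same protocols, the RNA was treated with DNase I, depleted of ribosomal RNA and digested with RNase R, an exonuclease that removes linear RNA and spares circles, before random-primed libraries were amplified by PCR and sequenced on a DNBSEQ instrument. No molecular identifiers are mentioned, so reads were not taken as independent molecules.

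The values analysed were CPM (reads scaled to the library total) for each circular RNA (circRNA) in each library, as deposited by the authors in 1 table with 1 column per library. Per the submitters' processing notes the genome build was hg38. The aligner, the back-splice caller, any filter on reads and the total used as the CPM denominator are not given in the sources used here. Each circRNA is named by its host gene and a number, and the genomic ends of the circles were not analysed here. For host genes, coordinates were taken from GENCODE release 29, which uses the same build, and 5363 of the 5685 host names matched a gene name there.

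Within each library every value above 0 was a whole multiple of 1 step, the worth of 1 read, and dividing by that step gave whole reads for 100% of the values within a tolerance of 0.0003 CPM. The inverse of the step gave the total behind the CPM, which was far above the sum of circRNA reads. Per library, these totals ran from 689513 to 20918203 reads and the circRNA reads from 325 to 136477. Shares of reads are given with Wilson 95% intervals, and where a circRNA had 0 reads the floor was set at 3 reads. Intervals and floors cover counting error only.

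Groups were taken from the sample titles, 3 libraries of ITGA6+ EVs and 3 of control EVs. The labels do not say that the libraries of a group came from separate cultures, so p-values measure only the spread between these samples, which may be technical. No 2 columns held identical values.

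The main test, fixed before the data were examined, was limma (version 3.58.1, R 4.3.3) with an intensity trend in the empirical Bayes step, on log2(CPM + 0.406), two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. The pseudocount was the median over the 6 libraries of the smallest value above 0. Features above 0 in at least 3 of the 6 libraries were tested, and no scaling beyond the CPM was applied. A fold change is therefore on the log2(CPM + pseudocount) scale. It can understate the change of low features, and a 0 in a shallow library, set at the pseudocount, can inflate it or turn its sign. The same fit was made on CPM summed over all circRNAs of a host gene. In both fits, also with the replicate number as a block, the empirical Bayes step gave infinite prior degrees of freedom. Each standard error and p-value thus came from the spread pooled along the trend, not from the feature's own spread. Where every library of a group was at 0, the fold was given as a bound, from the reads pooled over the other group against 3 reads over the pooled total of the group at 0. Such a bound covers counting error only. If reads are copies of fewer molecules, it is not a firm lower limit.

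Of the 13 gene lists fixed before the data were examined, those with at least 5 tested host genes were tested with limma's camera at a preset correlation of 0.01, with camera at an estimated correlation and with fry. Older gene symbols were matched to current ones. The numbers of detected circRNAs and host genes and the share of the 10 most abundant circRNAs were compared with exact two-sided permutation tests, for which 3 against 3 libraries cannot give a p below 0.1. Libraries were also thinned at random to 325 reads, the depth of the shallowest, 100 times each.

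The circRNAs named in the text followed a rule set beforehand. It took the 10 circRNAs with the highest and the 10 with the lowest fold change among those past the threshold and above 0 in all 3 libraries of the higher group, and open places were filled by the smallest unadjusted p. It added the 5 with the highest mean CPM in each group, up to 4 host genes per list by unadjusted p, all circRNAs of ITGA6, and 5 host genes in each direction. No listed circRNA carried ITGA6 as its host gene. Of what the rule took, 1 circRNA and its host gene are not reported here. Because no feature passed, every place was filled by unadjusted p, and in the higher direction only 9 circRNAs met the rule. The circRNAs found in all 6 libraries, those in every library of 1 group and no library of the other, the leading circRNA of control library 3 and the hosts with the most circRNAs were named after their values were seen.

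As alternatives, edgeR's quasi-likelihood test (version 4.0.16, TMM scaling) and DESeq2 (version 1.42.0) were run on the recovered reads, and each called 0 circRNAs and 0 host genes. Other alternatives were 3 other pseudocounts, 2 other filters, median centring and quantile normalization, no trend, the replicate number as a block, and leaving out each library in turn. Median centring aligned the libraries on the features above 0 in all 6, which were only 3 circRNAs or 4 host genes. It therefore did not centre the libraries on all tested features. Added after the data were seen were the removal of both libraries under 1000 circRNA reads, the 3 libraries above 10000 circRNA reads alone, edgeR with the totals behind the CPM as library sizes, and camera at an estimated correlation and fry with no filter.

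The limma and edgeR code was tested on simulated data for the ITGA6+ against control comparison of circRNAs at the real library totals, with 200 circRNAs changed. With counting noise alone, limma recovered 34.5% of those changed 4-fold, 82% of those changed 16-fold and 99% of those changed 64-fold, over 9322, 9261 and 9275 circRNAs tested. With the dispersion that edgeR estimated from the real reads, 1.95, the shares were 0%, 0% and 7.5%, over 5382, 5362 and 5476 circRNAs, and edgeR recovered 0% at each fold. Fewer circRNAs, 895, were above 0 in enough libraries to be tested in the real data. Other versions were Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.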

Results

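The cargo of circular RNA (circRNA), made when a splice donor joins an upstream acceptor, was sequenced from extracellular vesicles (EVs) of the bladder carcinoma line UM-UC-3. Vesicles carrying ITGA6, the integrin alpha subunit that pairs with ITGB1 or ITGB4 to bind laminin, gave 3 libraries. Vesicles labelled control gave 3. The table held 15113 circRNAs. Of these, 13639 carried the name of 1 of 5685 host genes, 161 were called intergenic and 1313 had no host gene in their name. Reads assigned to circRNAs numbered 1545, 101395 and 325 in ITGA6+ EV libraries 1, 2 and 3, and 55334, 136477 and 349 in control EV libraries 1, 2 and 3. These were 0.113% (Wilson 95% interval 0.107 to 0.119), 0.820% (0.815 to 0.825) and 0.0386% (0.0347 to 0.0431) of the library totals behind the CPM in ITGA6+ EVs. In control EVs the shares were 0.392% (0.389 to 0.396), 0.652% (0.649 to 0.656) and 0.0506% (0.0456 to 0.0562). A count of 3 reads, the floor for a circRNA at 0, was worth 2.19, 0.243 and 3.57 CPM in ITGA6+ EV libraries 1, 2 and 3, and 0.213, 0.143 and 4.35 CPM in control EV libraries 1, 2 and 3. Each group thus mixed deep and shallow libraries. In ITGA6+ EVs only library 2 was deep, while in control EVs libraries 1 and 2 were, so depth was not balanced between the groups.

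The first comparison asked whether ITGA6+ EVs held as broad a set of circRNAs as control EVs. hsa-PLEKHM1P1_0001, from the pseudogene copy of the lysosomal adaptor gene PLEKHM1, took 21.8% of the circRNA reads in ITGA6+ EV library 1 (337 reads, Wilson 95% interval 19.8 to 23.9) and 24.9% in library 3 (81 reads, 20.5 to 29.9). In ITGA6+ EV library 2 the leader was hsa-EXOC6B_0002, from an exocyst subunit gene, at 0.840% (852 reads, 0.786 to 0.898). The leaders of control EV libraries 1 and 2 were hsa-ASAP1_0077, from an Arf GTPase-activating protein gene, at 1.07% (593 reads), and hsa-UBXN7_0006, from a gene for a p97 adaptor, at 0.899% (1227 reads). In control EV library 3, hsa-MYO9B_0005 led with 4.87% (17 reads, 3.06 to 7.66). There hsa-PLEKHM1P1_0001 had 0 of 349 reads, which allows a share of up to 0.860%.

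The 10 most abundant circRNAs of each library together took 25.7% ± 18.5 of the reads in ITGA6+ EVs and 10.5% ± 8.14 in control EVs (SD, n = 3 per group; exact two-sided permutation test, p = 0.3, smallest possible p 0.1). In the deep libraries the share was 5.40% in ITGA6+ EV library 2 and 6.93% and 4.68% in control EV libraries 1 and 2. The number of circRNAs detected was 322, 3211 and 124 in ITGA6+ EV libraries 1, 2 and 3 and 4879, 10750 and 144 in control EV libraries 1, 2 and 3. The group means were 1219 ± 1728 and 5258 ± 5313 (SD, n = 3; exact permutation p = 0.3). Host genes detected numbered 844 ± 1126 and 2499 ± 2269 (SD, n = 3; exact permutation p = 0.3). At 325 reads per library, 189 ± 80.5 circRNAs were left in ITGA6+ EVs and 240 ± 86.3 in control EVs (SD, n = 3; exact permutation p = 0.5). These differences lay within the spread between libraries. At 325 reads the counts were 164, 279 and 124 in ITGA6+ EV libraries 1, 2 and 3. In control EV libraries 1, 2 and 3 they were 285, 294 and 140. The shallow libraries thus held fewer circRNAs than the deep ones at equal reads too. Summed circRNA CPM was 3239 ± 4313 and 3652 ± 3018 (SD, n = 3; exact permutation p = 0.9).

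**Figure D1:**
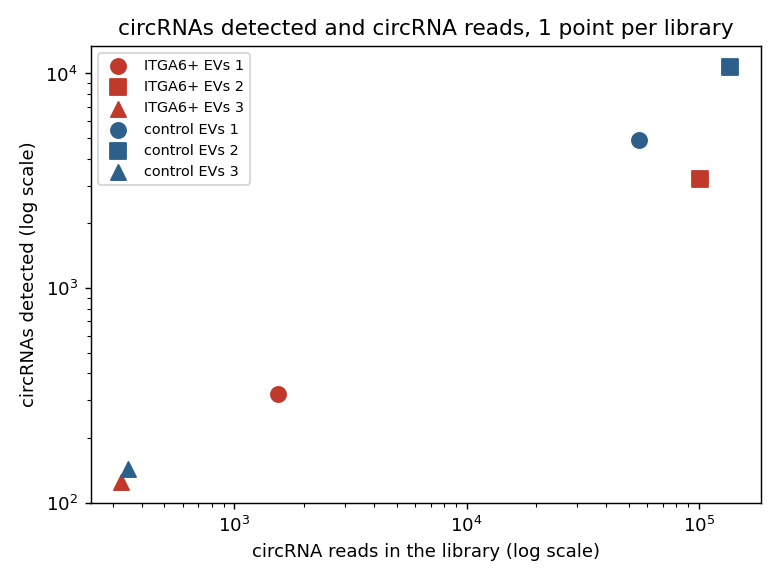
Number of circRNAs detected (vertical axis, log scale) against circRNA reads (horizontal axis, log scale), 1 point per library, with color for the group and shape for the library number. Detection followed depth from 124 circRNAs at 325 reads to 10750 at 136477 reads, and ITGA6+ EV library 2 held 3211 circRNAs at 101395 reads, below the 4879 that control EV library 1 held at 55334 reads.

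ITGA6+ EV library 3 held 124 circRNAs, which capped the number that all 6 libraries could share. Within that limit of depth few circRNAs were shared, since 11833 of the 15113 (78.3%) were found in 1 library only and 3 were found in all 6. These 3 were hsa-PVT1_0001, from the long noncoding RNA gene next to MYC (chromosome 8, 127794533 to 128101253, hg38), hsa-ASAP1_0077 (chromosome 8, 130052104 to 130443660) and hsa-GSE1_0001 (chromosome 16, 85169525 to 85676204). hsa-PVT1_0001 stood at 13.2, 5.50 and 7.13 CPM in ITGA6+ EV libraries 1, 2 and 3 and at 29.8, 6.12 and 4.35 CPM in control EV libraries 1, 2 and 3. hsa-GSE1_0001 stood at 8.77, 8.01 and 15.5 CPM against 28.3, 8.94 and 10.2 CPM. hsa-ASAP1_0077 stood at 8.77, 6.39 and 4.76 CPM against 42.1, 9.99 and 4.35 CPM. Their log2 fold changes were -0.21 (SE 1.47), -0.40 (SE 1.24) and -0.90 (SE 1.45), each smaller than its standard error.

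The second comparison asked which circRNAs were richer or poorer in ITGA6+ EVs. In the main limma fit, the smallest unadjusted p among the tested circRNAs was that of hsa-PLEKHM1P1_0001 (pseudogene at chromosome 17, 64779259 to 64837154, hg38). It had 246, 4.77 and 96.3 CPM in ITGA6+ EV libraries 1, 2 and 3. In control EV libraries 1, 2 and 3 it had 0.355, 2.49 and 0 CPM, where 0 allows up to 4.35 CPM. Its means were 116 ± 122 and 0.947 ± 1.34 CPM (SD, n = 3). Its log2 fold change was 5.69 (SE 1.69; limma Benjamini-Hochberg adjusted p = 0.702), against a median of -0.25 over all tested circRNAs. The log2 fold change was 4.54 without ITGA6+ EV library 1 and 7.33 without ITGA6+ EV library 2, the extremes with 1 library left out. It was 3.63 with 10 times the pseudocount and 1.80 in the 3 libraries above 10000 circRNA reads. The assignment to the pseudogene is uncertain, since its reads and those of its near-identical parent PLEKHM1 could be split by the counting. Both hosts together had 246, 10.1 and 96.3 CPM against 1.35, 6.65 and 0 CPM. In the other direction, hsa-ASXL1_0001, from a Polycomb-associated chromatin gene, stood at 0, 5.99 and 0 CPM in ITGA6+ EVs and 39.9, 10.6 and 5.80 CPM in control EVs (log2 fold change -3.78, SE 2.13; limma adjusted p = 0.999). With 1 library left out its log2 fold change ran from -5.11 (without ITGA6+ EV library 2) to -3.02 (without control EV library 1). It was -1.75 with 10 times the pseudocount and -1.72 in the 3 libraries above 10000 circRNA reads.

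Of 895 circRNAs tested, 0 were higher and 0 lower in ITGA6+ EVs past a limma Benjamini-Hochberg adjusted p of 0.05. At an unadjusted p under 0.05 limma had 1 circRNA higher, hsa-PLEKHM1P1_0001, and 0 lower, or 5 higher and 1 lower with quantile normalization. With 1 higher each, limma had 21 lower with the replicate number as a block, 8 lower without the intensity trend and 10 lower without ITGA6+ EV library 2. On the recovered reads edgeR and DESeq2 also called 0, with 1 higher and 32 lower in edgeR and 1 higher and 4 lower in DESeq2 at an unadjusted p under 0.05. The median standard error of a log2 fold change was 1.35. In the simulated data at the estimated dispersion, limma recovered 0% of 16-fold and 7.5% of 64-fold changes. The counts of 0 therefore do not exclude differences of that size. The limma adjusted p of hsa-PLEKHM1P1_0001 was 0.000483 with median centring on the 3 circRNAs found in all 6 libraries. That centring moved the median log2 fold change from -0.25 to 0.25. Over the limma alternatives the adjusted p of this circRNA ran from 7.97e-09 with no filter to 0.999. With edgeR and DESeq2 it ran from 0.361 to 1.00. In limma it was 0.0185 without the intensity trend and 0.0131 with the replicate number as a block. It was 0.00249, 1.89e-05 or 0.0274 without ITGA6+ EV library 2, control EV library 1 or control EV library 2.

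The other 8 circRNAs seen in all 3 ITGA6+ EV libraries with a higher fitted value all had 0 reads in control EV library 3, where 0 allows up to 4.35 CPM. hsa-MEIS3_0002, from a homeobox gene, had 4.14 ± 2.18 CPM in ITGA6+ EVs and 1.53 ± 2.49 CPM in control EVs (log2 fold change 2.01, SE 2.21). hsa-ATXN7_0001, from a gene of the SAGA acetyltransferase complex, had 3.85 ± 3.23 and 1.17 ± 1.48 CPM (1.63, SE 2.18). hsa-MARCH6_0047, from a ubiquitin ligase gene of the endoplasmic reticulum, had 5.98 ± 6.85 and 2.28 ± 2.03 CPM (1.23, SE 2.23). hsa-PSMA7_0001, from a proteasome subunit gene, had 3.07 ± 2.44 and 1.72 ± 1.54 CPM, and hsa-GRHPR_0002 5.69 ± 5.61 and 5.08 ± 5.11 CPM. For the remaining 3 the mean was lower in ITGA6+ EVs despite the positive fit. hsa-PILRB_0001 had 3.66 ± 1.38 and 4.09 ± 4.65 CPM, hsa-FKBP8_0005 5.28 ± 3.38 and 7.86 ± 6.83 CPM, and hsa-GOLPH3_0002, from a Golgi phosphoprotein gene, 7.25 ± 4.32 and 12.5 ± 11.6 CPM (SD, n = 3). The log2 fold changes of hsa-PSMA7_0001, hsa-GRHPR_0002, hsa-PILRB_0001, hsa-FKBP8_0005 and hsa-GOLPH3_0002 were 0.95, 0.66, 0.71, 0.35 and 0.33. All 8 fold changes lay under their standard errors, with a limma adjusted p of 0.999. Without control EV library 3 these 5 were -0.00341, -0.75, -0.57, -1.29 and -1.51, and those of hsa-MEIS3_0002, hsa-ATXN7_0001 and hsa-MARCH6_0047 were 1.32, 0.89 and 0.16.

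On the lower side, 9 of the 10 circRNAs that the rule took were at 0 in every ITGA6+ EV library, and hsa-ASXL1_0001 was the exception. hsa-CPT1A_0010, from the gene for the carnitine palmitoyltransferase of fatty acid oxidation, had 4.33 ± 4.12 CPM in control EVs. hsa-LIN52_0001, from a cell cycle repressor complex gene, had 3.11 ± 2.33 CPM. hsa-DCLK2_0001, from a doublecortin-like kinase gene, had 2.64 ± 1.48 CPM, and hsa-EIF3H_0028, from a translation initiation factor gene, had 2.49 ± 2.96 CPM. hsa-NF2_0001, from the gene for the tumor suppressor merlin, had 2.42 ± 1.70 CPM and hsa-PPP1R12C_0005 2.23 ± 1.86 CPM. hsa-TRIO_0025 had 1.91 ± 1.17 CPM, and hsa-BARD1_0008, from the gene for a partner of BRCA1, had 1.72 ± 0.233 CPM (SD, n = 3). The limma adjusted p of each was 0.999, which rests on the pooled spread and not on the SDs given. In control EV library 3 each of these 8 rested on 1 to 6 reads. Without that library the control means of hsa-CPT1A_0010, hsa-LIN52_0001, hsa-EIF3H_0028, hsa-NF2_0001 and hsa-PPP1R12C_0005 were 2.14, 1.77, 0.828, 1.45 and 1.16 CPM. Those of hsa-DCLK2_0001, hsa-TRIO_0025 and hsa-BARD1_0008 were 2.51, 1.41 and 1.85 CPM.

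**Figure D2:**
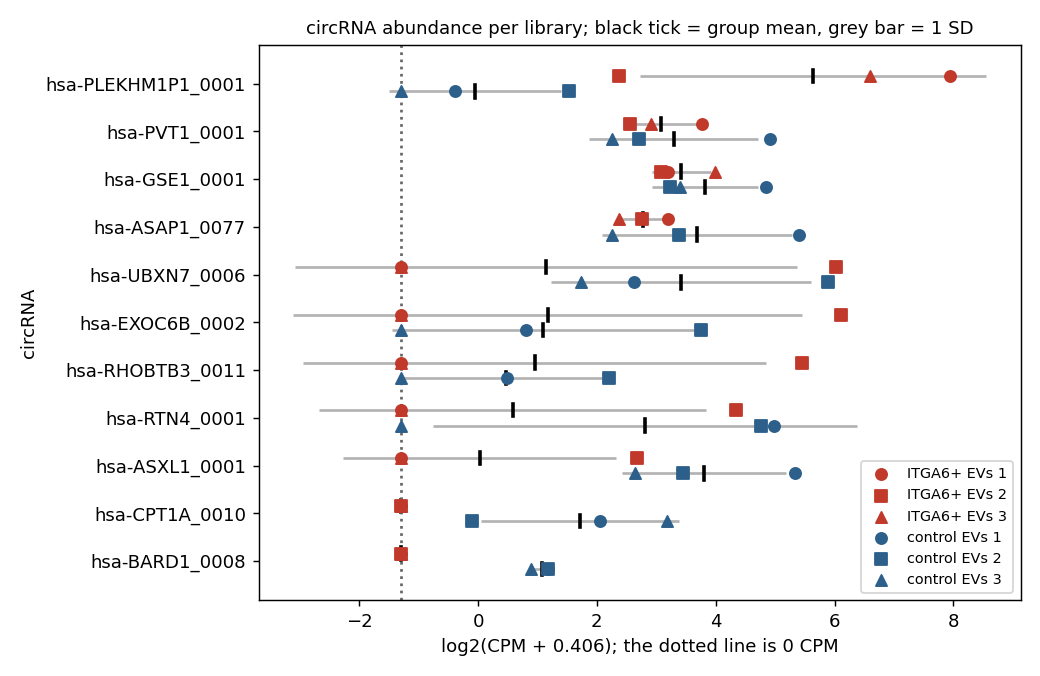
Abundance of 11 circRNAs on the log2(CPM + 0.406) scale (horizontal axis), 1 point per library, with color for the group, shape for the library number, a black tick for the group mean and a grey bar for 1 SD. hsa-PLEKHM1P1_0001 lies at 246 and 96.3 CPM in ITGA6+ EV libraries 1 and 3, while hsa-EXOC6B_0002 and hsa-RHOBTB3_0011 owe their ITGA6+ EV mean to library 2 alone.

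By mean CPM, the 5 most abundant circRNAs of ITGA6+ EVs were hsa-PLEKHM1P1_0001, hsa-EXOC6B_0002, hsa-UBXN7_0006, hsa-ZNF292_0001 and hsa-RHOBTB3_0011. Apart from the first, their level came from library 2. hsa-EXOC6B_0002 had 0, 68.9 and 0 CPM, and hsa-UBXN7_0006 had 0, 64.5 and 0 CPM. hsa-ZNF292_0001 had 2.19, 42.9 and 0 CPM, and hsa-RHOBTB3_0011 had 0, 43.5 and 0 CPM. In control EVs these 4 stood at 4.83 ± 7.23, 22.4 ± 31.4, 4.27 ± 3.91 and 1.73 ± 2.20 CPM (SD, n = 3). The 5 most abundant circRNAs of control EVs were hsa-UBXN7_0006, hsa-RTN4_0001 from the reticulon gene RTN4, hsa-ASAP1_0077, hsa-ASXL1_0001 and a circRNA of the noncoding locus RP11-1023L17. hsa-RTN4_0001 had 19.3 ± 16.9 CPM in control EVs and 6.63 ± 11.5 CPM in ITGA6+ EVs, and the RP11-1023L17 circRNA had 17.2 ± 8.67 and 11.5 ± 12.7 CPM (SD, n = 3). None of the 9 circRNAs in these lists passed the limma test, with adjusted p = 0.702 for hsa-PLEKHM1P1_0001 and 0.999 for the others.

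The third comparison summed the circRNAs of each host gene. PLEKHM1P1 had 1 circRNA and so the same values, 116 ± 122 CPM in ITGA6+ EVs and 0.947 ± 1.34 CPM in control EVs (log2 fold change 5.69, SE 1.87; limma adjusted p = 0.999). CDKAL1, a tRNA-modifying enzyme gene, had 4.62 ± 0.913 and 3.54 ± 5.96 CPM, with 10.4 CPM in control EV library 2. ATXN7 had 3.85 ± 3.23 and 1.28 ± 1.44 CPM, MARCH6 had 6.74 ± 8.15 and 2.83 ± 2.73 CPM, and MEIS3 had 4.14 ± 2.18 and 1.53 ± 2.49 CPM (SD, n = 3). On the lower side, KCNMA1, the gene of the large-conductance calcium-activated potassium channel, had 0 reads in ITGA6+ EVs and 124 reads, 4.66 ± 3.51 CPM, in control EVs. By counting error alone it was at least 16.9-fold lower over the pooled libraries. The bound was 2.56-fold without ITGA6+ EV library 2, 4.27-fold without control EV library 1, which held 105 of the reads, and 35.8-fold without control EV library 2. The bounds were 13.7-fold for RAB3GAP1, a Rab regulator gene, 10.9-fold for DCLK2, 10.6-fold for LIN52 and 8.30-fold for NF2, all with 0 reads in ITGA6+ EVs. These 4 bounds were 2.08, 1.65, 1.61 and 1.26-fold without ITGA6+ EV library 2, which gave 12364206 of the reads pooled for ITGA6+ EVs, against 1367843 and 841162 in libraries 1 and 3. Without control EV library 2 the bound of RAB3GAP1 was 4.60-fold, and without control EV library 1 or 2 that of DCLK2 was 5.40 or 19.1-fold. In ITGA6+ EV library 2 the median was 18 reads per detected circRNA. If those reads are copies of fewer molecules, 0 reads there allows more than the floor. None of these bounds is thus a firm lower limit.

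Of 1187 host genes tested, limma called 0 higher and 0 lower, with 1 higher (PLEKHM1P1) and 0 lower at an unadjusted p under 0.05. With quantile normalization the limma counts at that level were 7 higher and 1 lower. With 1 higher each, they were 36 lower with the replicate number as a block, 10 lower without the intensity trend and 23 lower without ITGA6+ EV library 2. The count tests edgeR and DESeq2 also called 0, with 3 higher and 27 lower in edgeR and 4 higher and 4 lower in DESeq2 at an unadjusted p under 0.05. PLEKHM1P1 passed in limma with median centring, which moved the median log2 fold change from -0.37 to 0.19 (adjusted p = 0.0169), with the replicate number as a block (adjusted p = 0.0119) and without control EV library 1 (adjusted p = 0.00122), in a range over all alternatives from 0.00122 to 1.00.

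The fourth comparison took the gene lists. Median centring rested here on the 4 host genes above 0 in all 6 libraries. Of the 1187 tested hosts, 1038 were above 0 in ITGA6+ EV library 2 and control EV libraries 1 and 2, the 3 deep ones. A 0 in a shallow library was set at the pseudocount, which favours lower fitted values in ITGA6+ EVs. Counts of lower members are thus no evidence about a list. In the 3 deep libraries alone the median log2 fold change of all hosts was 0.89, and the lists were not tested there. The integrin and focal adhesion list had 6 tested host genes, 2 with a higher and 4 with a lower fitted value (median log2 fold change -0.59; 3 and 3 with median centring). It included PTK2, the focal adhesion kinase gene, at 2.92, 40.1 and 1.19 CPM in ITGA6+ EV libraries 1, 2 and 3 and 29.5, 19.4 and 1.45 CPM in control EV libraries 1, 2 and 3. VCL, the vinculin gene, had 1.05 ± 1.82 CPM in ITGA6+ EVs and 0.261 ± 0.249 CPM in control EVs. ROCK2 had 0.836 ± 1.45 and 2.03 ± 1.92 CPM, and ARHGEF7 0.189 ± 0.327 and 0.636 ± 0.763 CPM (SD, n = 3). VCL, ROCK2 and ARHGEF7 were at 0 in ITGA6+ EV libraries 1 and 3, which were shallow. All 11 tested hosts for vesicle formation and endosomal sorting had a lower fitted value (median -0.66, also with EEA1 at its bound), but 6 of 11 with median centring, and 9 of 11 lay below the median of all host genes, -0.37. EEA1, the early endosome tether gene, was at 0 in ITGA6+ EVs and 1.80 ± 2.24 CPM in control EVs (4.35 CPM in library 3). By counting error alone it was at least 2.58-fold lower over the pooled libraries. Without ITGA6+ EV library 2 that bound was 0.392, so no difference was detectable, and without control EV library 1 or 2 it was 1.57 or 4.93. SNX1, a retromer gene, had 0.270 ± 0.467 and 1.70 ± 2.65 CPM. RAB31 had 0.108 ± 0.187 and 0.756 ± 1.13 CPM, and PIKFYVE, an endosomal lipid kinase gene, 1.02 ± 1.77 and 1.72 ± 1.85 CPM. SNX1, RAB31 and PIKFYVE reads in ITGA6+ EVs came from library 2 alone.

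Of 15 RNA-binding protein genes, 2 had a higher and 13 a lower fitted value (median -0.67), or 7 and 8 with median centring. RBM33 summed to 3.33 ± 3.89 CPM in ITGA6+ EVs and 0.702 ± 1.17 CPM in control EVs, HNRNPC to 1.83 ± 3.18 and 4.34 ± 4.35 CPM, and PTBP3 to 0.431 ± 0.747 and 1.33 ± 1.48 CPM (SD, n = 3). Well-known circRNA hosts counted 34 tested genes, 8 higher and 26 lower (median -0.44), or 21 and 13 with median centring. They held 4.04%, 7.29% and 12.5% of the host-assigned reads in ITGA6+ EV libraries 1, 2 and 3 and 7.37%, 5.52% and 8.60% in control EV libraries 1, 2 and 3. Within this list FNDC3B had 0.297 ± 0.514 and 5.60 ± 5.25 CPM, CRIM1 1.86 ± 3.22 and 6.18 ± 5.26 CPM, and UBXN7 22.4 ± 38.8 and 23.8 ± 31.5 CPM. Of 27 chromatin regulators, 6 were higher and 21 lower (median -0.43), or 15 and 12 with median centring. ASXL1 had 3.85 ± 5.67 and 21.1 ± 21.9 CPM. EHMT1, a histone methyltransferase gene, had 0.450 ± 0.645 and 2.64 ± 0.644 CPM, KANSL1 4.10 ± 7.10 and 7.67 ± 5.43 CPM, and BAZ1B 0.162 ± 0.280 and 0.895 ± 0.789 CPM (SD, n = 3). In ITGA6+ EVs the reads of HNRNPC, PTBP3, FNDC3B, CRIM1, UBXN7, KANSL1 and BAZ1B came from library 2 alone.

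The 8 tested bladder cancer driver genes split into 4 higher and 4 lower (median 0.0256), or 7 and 1 with median centring. ASXL1, which is also on this list, had the smallest unadjusted p in it and was lower (log2 fold change -2.98, SE 2.02). ERBB2, the HER2 receptor gene, had 2.92, 5.90 and 0 CPM in ITGA6+ EV libraries 1, 2 and 3 and 0.213, 0.287 and 0 CPM in control EV libraries 1, 2 and 3 (log2 fold change 1.87, SE 1.60). ERBB3 had 0.621 ± 0.574 and 0.112 ± 0.193 CPM, and EP300, a histone acetyltransferase gene, 3.15 ± 5.46 and 0.310 ± 0.478 CPM. Cell cycle and centrosome hosts counted 7, of which 1 was higher and 6 lower (median -0.42), or 4 and 3 with median centring. CEP128, a centriole appendage gene, was at 0.431 ± 0.747 and 4.44 ± 1.33 CPM and CDK14 at 0.675 ± 0.649 and 3.27 ± 3.26 CPM. STAG1, a cohesin gene, was at 1.32 ± 2.29 and 1.42 ± 1.42 CPM, and CDK8 at 0.485 ± 0.841 and 0.676 ± 0.882 CPM (SD, n = 3). Of 24 ubiquitin ligase genes, 7 were higher and 17 lower (median -0.38, also with FBXW8 at its bound), or 17 and 7 with median centring. FBXW8 was at 0 in ITGA6+ EVs and 1.31 ± 0.406 CPM in control EVs. By counting error alone it was at least 6.39-fold lower over the pooled libraries. Without ITGA6+ EV library 2 the bound was 0.969 and no difference was detectable. HACE1 had 0.270 ± 0.467 and 4.14 ± 3.75 CPM, NEDD4 0.270 ± 0.467 and 4.63 ± 7.25 CPM, and ITCH 0.0539 ± 0.0934 and 0.308 ± 0.320 CPM. Motility, epithelial and mesenchymal genes counted 15, 3 higher and 12 lower, or 10 and 5 with median centring. ARHGEF28 was at 2.84 ± 3.78 (7.13 CPM in library 3) and 0.356 ± 0.395 CPM and ZEB1, a mesenchymal transcription factor gene, at 1.32 ± 2.29 and 2.91 ± 2.78 CPM. TIAM1 was at 0.350 ± 0.607 and 1.42 ± 1.77 CPM, and MYH9 at 0.243 ± 0.420 and 0.857 ± 0.861 CPM (SD, n = 3). In ITGA6+ EVs the reads of EP300, CEP128, STAG1, CDK8, HACE1, NEDD4, ITCH, ZEB1, TIAM1 and MYH9 came from library 2 alone.

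None of the 9 lists tested passed camera in limma (Benjamini-Hochberg adjusted p from 0.528 to 0.963), none passed at an estimated correlation (adjusted p = 0.982 for each) and none passed fry (adjusted p from 0.888 to 0.985). In no list did a member pass over all genes tested or adjusted over the list alone, where the count was 0. The motility list had a median log2 fold change of -0.42 and a mean of -0.34 while camera put it upward, and all host genes together had a median of -0.37. Lists of other cell types were nearly empty, with 4 endothelial, 4 blood and immune and 5 fibroblast markers among the hosts. They held at most 0.0221%, 0.0457% and 0.0751% of the host-assigned reads in any library. Of the mitochondrially encoded genes, 0 were hosts.

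The last comparison counted circRNAs found in every library of 1 group and no library of the other. There were 25 such circRNAs in control EVs and 0 in ITGA6+ EVs. The shallow ITGA6+ EV libraries 1 and 3 shared only 12 circRNAs, which capped the count in ITGA6+ EVs. Control EV library 3 shared 82 and 79 with control EV libraries 1 and 2. The depths of the libraries thus favoured this direction, and the asymmetry is no evidence of a group difference. hsa-DCLK2_0001 had 80 reads in control EVs. By counting error alone it was at least 10.9-fold lower in ITGA6+ EVs over the pooled libraries, where 3 reads were worth 0.206 CPM. This and the bounds below are not firm lower limits, since reads may be copies of fewer molecules. The bounds were 9.93-fold for hsa-CRIM1_0025, 9.52-fold for hsa-CPT1A_0010, 8.98-fold for hsa-BARD1_0008, 8.84-fold for hsa-LIN52_0001 and 7.62-fold for hsa-NF2_0001. Most of the pooled depth was that of ITGA6+ EV library 2. Without it 3 reads were worth 1.36 CPM, and the bounds of these 6 were 1.65, 1.51, 1.44, 1.36, 1.34 and 1.15-fold. Without control EV library 1 or 2 the bound was 5.40 or 19.1-fold for hsa-DCLK2_0001 and 3.82 or 19.4-fold for hsa-CPT1A_0010, and for hsa-CRIM1_0025 it was 2.63-fold without control EV library 2. The bounds of hsa-TRIO_0025, hsa-PPP1R12C_0005 and hsa-EIF3H_0028 were 6.26, 5.71 and 3.81-fold, but 0.949, 0.866 and 0.577 without ITGA6+ EV library 2. Without control EV library 1 or 2 those of hsa-TRIO_0025 were 3.37 or 10.8-fold and those of hsa-EIF3H_0028 1.35 or 8.54-fold. For 24 of the 25 the bound was above 1, or for 7 of the 25 without ITGA6+ EV library 2, and for hsa-UTP20_0001, at 0.952, no difference was detectable at this depth. The count leaned on the shallow libraries, since 12 of the 25 rested on 1 read in control EV library 3. In either direction the count became 1219 without control EV library 3, 45 without ITGA6+ EV library 2 and 44 without control EV library 2, and 2.1 on average when all libraries were thinned to 325 reads.

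**Figure D3:**
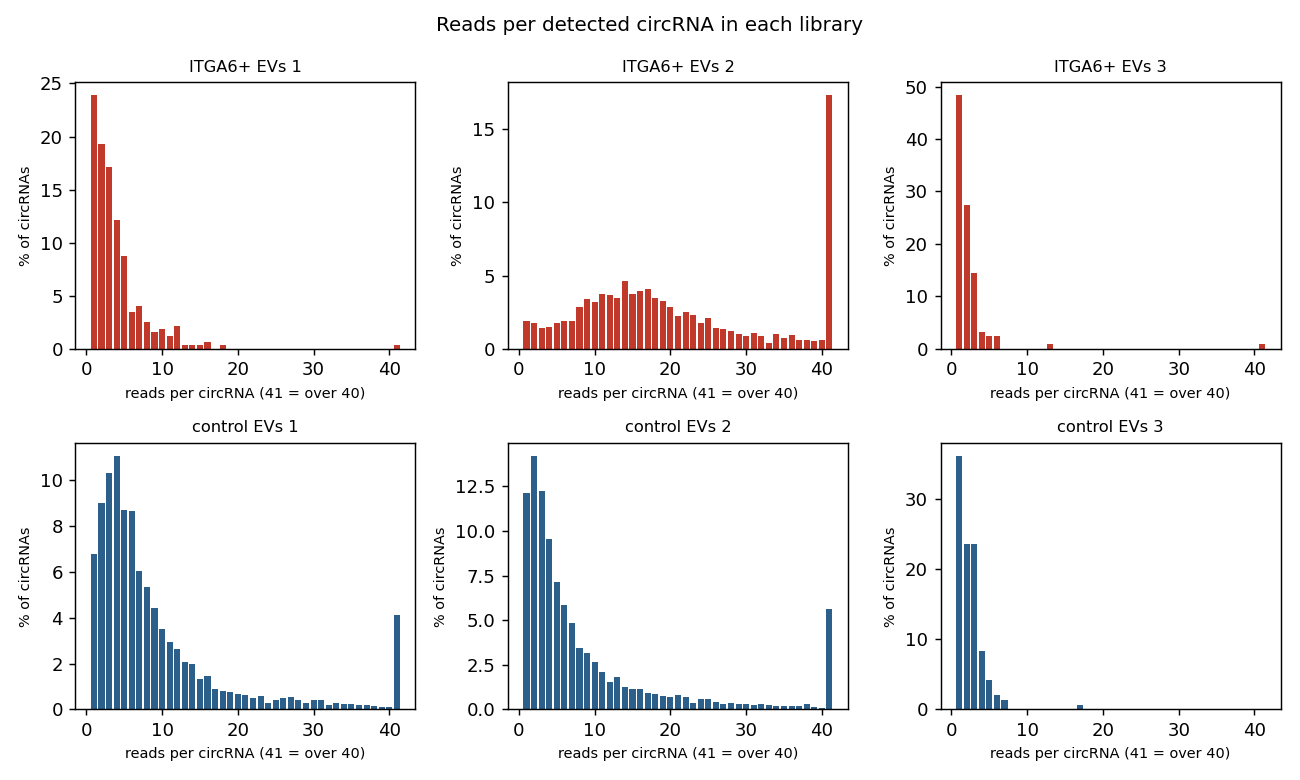
Share of detected circRNAs (vertical axis, percent, a separate scale in each panel) by their number of reads (horizontal axis, with all above 40 pooled at 41), 1 panel per library. The most common number was 14 reads in ITGA6+ EV library 2, against 4 and 2 reads in control EV libraries 1 and 2.

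Reads were spread differently over the circRNAs of the deep libraries. In ITGA6+ EV library 2 the median was 18 reads per detected circRNA and 61 of its 3211 circRNAs (1.90%) had 1 read. In control EV libraries 1 and 2 the medians were 6 and 5 reads, and 6.78% and 12.1% of the circRNAs had 1 read.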

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

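The removal of both libraries under 1000 circRNA reads, the 3 libraries above 10000 circRNA reads alone, edgeR with the totals behind the CPM, and the other list tests with no filter were chosen after seeing the data, and the other alternatives were set before the data were examined. The counts of 0 lower circRNAs and 0 lower host genes held under every alternative run. The difference in detected circRNAs kept its direction in each alternative run for it. The difference in the share of the 10 most abundant did so except in the 3 libraries above 10000 reads, where it was -0.410 percentage points. The count of circRNAs higher in ITGA6+ EVs became 1, hsa-PLEKHM1P1_0001, with no filter, median centring or no trend, and 0 to 1 when 1 library was left out (1 without ITGA6+ EV library 2, control EV library 1 or control EV library 2). For host genes it became 1, PLEKHM1P1, with median centring, and 0 to 1 with 1 library left out (1 without control EV library 1). With no filter 1 of 10 gene lists passed camera, the fibroblast and stromal markers (upward, adjusted p = 0.0240 at the preset correlation). The reads of its 5 hosts all lay in ITGA6+ EV library 2 or control EV library 2, and 0 of them met the usual filter. With no filter, 0 lists passed at an estimated correlation or with fry, where this list had adjusted p = 0.988 and 0.666. At the preset correlation the lowest adjusted p of any list ran from 0.0240 to 0.842 over the alternatives. No list could be tested on host genes above 0 in all 6 libraries. The 25 circRNAs in every library of 1 group and none of the other became 13 when 2 reads were required, 2.1 on average after thinning, 1253 without both libraries under 1000 reads, 2657 in the 3 libraries above 10000 reads, and 31 to 1219 with 1 library left out, the highest without control EV library 3. Fewer libraries to meet the condition raise this count by construction. The causes of the other changes were not tested.

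Whether the replicate numbers pair the libraries stays open. The correlations of same-numbered deviations were 0.0977, 0.42 and 0.32. Those of differently numbered deviations ran from -0.38 to 0.16, the highest between ITGA6+ EV library 1 and control EV library 3. The libraries numbered 2 were both deep and those numbered 3 both shallow, so these correlations cannot tell pairing from depth. With the replicate number as a block, limma called 1 circRNA (hsa-PLEKHM1P1_0001) and 1 host gene (PLEKHM1P1) higher and 0 lower, and edgeR with that block called 0.

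Of 1252 values of 70 named circRNAs and host genes under alternatives, 57 values of 20 of them turned sign, all uncalled, and 10 passed the threshold in the same direction. Turned log2 fold changes were -0.44, -0.61, -1.12 and -1.09 for hsa-PILRB_0001, hsa-GRHPR_0002, hsa-GOLPH3_0002 and hsa-FKBP8_0005 with edgeR and TMM. Without both libraries under 1000 reads these 4 had -0.32, -0.65, -0.90 and -1.31, and ARHGEF28 had -0.0924. In the 3 libraries above 10000 reads, hsa-PILRB_0001, hsa-GOLPH3_0002 and hsa-FKBP8_0005 had -0.58, -0.77 and -0.39, while hsa-UBXN7_0006 had 1.77, the RP11-1023L17 circRNA 0.17, PTK2 0.74, PIKFYVE 0.32, UBXN7 1.54, KANSL1 0.37, STAG1 0.84 and CDK8 0.57. With edgeR on the CPM totals, hsa-PILRB_0001 had -0.19, hsa-GOLPH3_0002 -0.79 and hsa-FKBP8_0005 -0.58. With 10 times the pseudocount hsa-GOLPH3_0002 had -0.25 and hsa-FKBP8_0005 -0.17, and with the pseudocount at 0.203 hsa-EXOC6B_0002 had -0.19. With edgeR and the block, hsa-GOLPH3_0002 had -0.38, hsa-FKBP8_0005 -0.56 and hsa-EXOC6B_0002 -0.44. With DESeq2, hsa-GOLPH3_0002 had -0.35, hsa-UBXN7_0006 0.16, PTK2 0.89, UBXN7 0.29, STAG1 1.03, CDK8 0.00911 and ZEB1 0.12. Median centring gave CDK8 0.21 and ITCH 0.0179, and quantile normalization gave 0.0448 and 0.0377. With 1 library left out the ranges were -0.00341 to 1.52 for hsa-PSMA7_0001, -0.57 to 1.71 for hsa-PILRB_0001, -0.75 to 1.61 for hsa-GRHPR_0002 and -1.51 to 1.40 for hsa-GOLPH3_0002. They were -1.29 to 1.20 for hsa-FKBP8_0005, -1.11 to 1.32 for hsa-EXOC6B_0002, -1.36 to 2.01 for hsa-ZNF292_0001, -0.39 to 1.61 for hsa-RHOBTB3_0011, and -2.98 to 0.0105 for the RP11-1023L17 circRNA. For host genes they were -0.0183 to 1.91 for MARCH6, -2.16 to 0.17 for PTK2 and -0.90 to 0.0112 for CDK8. The median log2 fold change of all circRNAs was -0.25 as reported, 0.25 with median centring, 0.06 with quantile normalization and 0.65 with DESeq2. Median centring and the DESeq2 size factors both rested on the 3 circRNAs found in all 6 libraries. This median was -0.67 with edgeR and TMM, -1.14 with edgeR and the block, and -0.84 without control EV library 3. In the 3 libraries above 10000 reads it was 1.01. Depth limits the values that use the 3 libraries with 1545 reads or fewer, since 1 read was worth at least 0.731 CPM in each. In simulated data with all libraries at the deepest total, limma recovered 89.5% of 4-fold changes with counting noise alone, against 34.5% at the real totals. At the dispersion estimated from the real reads it recovered 8% of 64-fold changes, against 7.5%. That dispersion was estimated with the shallow libraries included and was kept unchanged, so what more depth would add is not decided.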

Other observations

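The test of the groupings for circRNAs in every library of 1 group was set before the data were examined, and all other tests of explanations in this part were chosen after the results were seen. Host genes differed in how many circRNAs they gave. PTK2, the focal adhesion kinase gene, gave 34, of which 26 were seen in control EV library 2, 21 in control EV library 1 and 7 in ITGA6+ EV library 2. SMARCC1 gave 25, BIRC6 21, ABCC1 20 and UBAP2 19, while 2673 of the 5685 hosts gave 1. The long noncoding RNA gene CASC15 gave 20 circRNAs, 19 of them in control EV library 2 at 42.3 CPM together, against 1 at 2.55 CPM in control EV library 1, 1 at 6.58 CPM in ITGA6+ EV library 1 and 0 in ITGA6+ EV library 2. USP34, a deubiquitinase gene, gave 7 at 17.7 CPM in ITGA6+ EV library 2 and 12 at 7.65 CPM in control EV library 2.

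More sharing is expected with a library that holds more circRNAs, and the libraries held 322, 3211 and 124 in ITGA6+ EV libraries 1, 2 and 3 and 4879, 10750 and 144 in control EV libraries 1, 2 and 3. Of the 124 circRNAs of ITGA6+ EV library 3, 12 and 35 were also in ITGA6+ EV libraries 1 and 2, and 69, 68 and 7 were in control EV libraries 1, 2 and 3. ITGA6+ EV library 2 shared 1736 of its 3211 circRNAs with control EV library 2 and 882 with control EV library 1, and the 2 control libraries shared 2064. Across the tested circRNAs the log2 values of ITGA6+ EV library 2 correlated with control EV library 2 at r = 0.51 and with ITGA6+ EV libraries 1 and 3 at r = -0.14 and -0.09, where circRNAs are not independent replicates. Of the 895 tested, 646 were in all 3 deep or all 3 shallow libraries and in none of the others. The low r with ITGA6+ EV libraries 1 and 3 thus follows largely from the filter and depth, and does not compare the groups.

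The 6 libraries can be parted into 3 and 3 in 10 ways, too few for a share under 0.05. The real grouping gave 0 circRNAs, 0 host genes and 0 gene lists past the threshold, so all 10 groupings gave as many, and the highest of the others gave 572 circRNAs, 805 host genes and 1 list. For circRNAs in every library of 1 group and none of the other, 4 of the 10 groupings gave at least the real 25, and the highest other gave 646. The grouping with 572, 805 and 646 set ITGA6+ EV libraries 1 and 3 and control EV library 3 apart from the other 3. This points to a structure of the samples that goes along with read depth. The shallow libraries also held fewer circRNAs at 325 reads each, 124 to 164 against 279 to 294.

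The circRNA hsa-PLEKHM1P1_0001 took over 20% of the circRNA reads of ITGA6+ EV libraries 1 and 3. Reads of the parent gene PLEKHM1 given to its pseudogene copy, at an unchanged sum, would leave both genes together near the control level. In the lower of the 2 libraries they were together at 14.5 times the highest control library, which argues against that. A rise of a PLEKHM1 circle counted under the pseudogene would raise the sum alike, and with PLEKHM1 at 0 CPM in both libraries the gene of origin stays open. Amplification accidents arising apart in each library stay open, because the circRNA led 2 libraries, those in which it was noticed, and none of the other 4. Low depth stays open, because only 1 control library was as shallow and its upper limit of 0.860% is that of a single library. A candidate explanation that was not tested is carry-over of 1 product between the 2 libraries, and a real enrichment in ITGA6+ EVs, which library 2 at 0.0582% of its reads did not share in size, is also untested.

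In ITGA6+ EV library 2 the reads per circRNA peaked at 14, far above 1. Depth is argued against, since at 55334 reads per library its median was still 10 reads per circRNA, against 6 in control EV library 1 and 2.85 in control EV library 2. A minimum number of reads set upstream within this library is argued against by the 61 circRNAs listed with 1 read. A minimum that a circRNA could meet in another library, or over the libraries together, was not tested and stays open. When 50% of its reads were kept it lost 1.80% of its circRNAs, against 8.0% and 12.1% in control EV libraries 1 and 2. That loss follows from the reads per circRNA themselves, so it does not decide whether few starting molecules were each copied many times. This and a smaller set of circRNAs in the captured vesicles, which was not tested, stay open, and the pattern is seen in 1 library.

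Of the 3 circRNAs in all 6 libraries, those of PVT1 and ASAP1 come from hosts close together on chromosome 8, at 127794533 to 128101253 and 130052104 to 130443660. Raised copy number or expression of the whole stretch could account for this, but the other 4 hosts from PCAT1 (start 126556323) to EFR3A (start 131904088), which were EFR3A, FAM49B, PCAT1 and GSDMC, had a median rank at the 42.1 percentile of mean CPM. With 4 hosts, from the 75.7 percentile for EFR3A to the 1.67 percentile for GSDMC, this decides nothing, and no biological explanation was tested.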
